A study of Homo sapiens with 6 samples.

How the data were processed

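Gene expression was measured by RNA sequencing in LU65, an established human lung cancer cell line that carries the KRAS G12C allele. The 6 libraries fall into 3 from parental cells without treatment and 3 from a derived line that had been selected in RMC-4998 and was kept in the drug, per the labels. Some file names carry a code other than this compound name, and the labels were followed. RMC-4998 is an inhibitor that binds KRAS G12C together with cyclophilin A, the product of PPIA. Per the labels' protocols, the dose was raised by doubling over 4 to 6 passages and then held at 200 nM, and each library was made from 1.3 µg of total RNA with a SMARTer mRNA kit. The series calls the samples biological triplicates. Since the resistant cells were maintained in drug and the parental cells were not, selection and the presence of drug cannot be separated in any comparison. The resistant libraries come from a single derived line, so p-values measure spread between libraries of that line and not between independent derivations. Differences that arose in this derivation without bearing on resistance cannot be separated either.

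The authors deposited estimated counts (expected counts) per gene for each library, with no scaling between libraries. Between 93.5% and 95.2% of the values were whole numbers and the others had 2 decimals, and all were rounded to whole numbers before use. The aligner and the counting tool are not given in the sources used here. Per the submitters' processing notes, the genome builds were GRCm38 and mm10, which are mouse builds, whereas the deposited gene identifiers are human Ensembl identifiers. The build used for counting is therefore not known, and coordinates are those of GENCODE 29 on the human reference GRCh38. Of the 58870 identifiers in each file, 58597 were found in GENCODE 29 when versions were ignored (47456 with the same version), and 58472 had a symbol in the gene name table. Whether counting used strand is not given, so reads of overlapping and antisense genes cannot be told apart, and values of close paralogs and of genes with many pseudogenes (cystatins, serum amyloids, keratins, HLA, histones, ribosomal proteins, PPIA, the UGT1A genes that share exons) are uncertain.

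Total counts were 75118133, 84476264 and 78622917 in parental libraries 1 to 3 and 69977671, 78921049 and 48070428 in resistant libraries 1 to 3. CPM values, counts scaled to library size, were computed with the TMM factors of edgeR and are given as mean ± SD over 3 libraries. Intervals pool the reads of the 3 libraries of a group, so they cover counting error only and leave out the spread between libraries. Floors cover counting error only as well, and the reads carry no molecular identifiers. Where a group had no read, the fold is a lower bound against a floor of 3 counts per library. Where it had few reads, the ratio has an exact 95% interval.

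Differential expression was tested, two-sided, with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit with robust estimation, group as the only term) in R 4.3.3, after filterByExpr and TMM scaling. P-values were adjusted by Benjamini-Hochberg, and genes under 0.05 are called changed. Standard errors of log2 fold changes were obtained by dividing the fold change by the square root of F. All adjusted p-values of single genes are from this test. On counts simulated for resistant versus parental over 18637 tested genes, with 200 genes changed (186 of them tested) and the 25 genes of a list shifted by 0.5 on the log2 scale, the test recovered all 41 genes (100%) changed 2-fold and 33 of 43 (76.7%) changed 1.5-fold among those of at least 10 CPM. Over all levels it recovered 47 of 94 (50%) and 33 of 92 (35.9%), and of its 101 calls 13 were genes of the shifted list and 8 (7.92%) were false.

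A total of 35 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 35 lists. Camera compares a list with all other genes. An estimated correlation and fry served as alternatives. In the simulation the shifted list was called by all 3 tests and 0 of 35 unshifted lists were. Genes were simulated independently of each other, so this does not show how often the tests call lists of correlated genes falsely. The lists cover RAS and MAPK signalling, receptors and ligands, PI3K signalling, cell state and lineage, proliferation, immune and inflammatory genes, stress and metabolism, adhesion, markers of other cell types, and RNA quality.

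Genes are named by a rule set before the data were examined. It takes KRAS, PPIA, DUSP6, SPRY4, ETV4, ETV5, CCND1 and MYC in any case, the 10 largest rises and 10 largest falls among changed protein-coding genes with at least 10 CPM in the higher group and no overlap between groups, the 3 lowest p-values, and the members with the lowest adjusted p in each list (3 or 4 in called lists, up to 2 in others). Other genes named as members of a list were chosen after their values were seen.

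Alternatives set beforehand were DESeq2 1.42.0 size factors and its Wald test, limma-voom, library-size scaling, no filter, a filter of 5 CPM in 3 libraries, glmTreat against 1.5-fold, a replicate block, and leaving out each library in turn. Added after the data were seen were a background subtraction, which takes off each gene's count the read density at olfactory receptor genes times its exonic length, and a fit that keeps resistant library 2 as the only resistant library. Chi-square per degree of freedom between libraries of a group was 15.6 to 45.5, so no library was a copy of another. XIST and Y-linked genes were left out. Figures were drawn with matplotlib 3.10.9.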

Results

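The study profiled the transcriptome of LU65 cells and of a line derived from them that grows in the KRAS G12C inhibitor RMC-4998, with 3 libraries per group and 48070428 to 84476264 counts per library. Correlations of log2 CPM were at least 0.979 within a group and at most 0.875 between groups, and the first principal component held 74.1% of the variance. Resistant library 2 stood apart from resistant libraries 1 and 3, at 77.4 against 145 and 142 on the first component and -91.5 against 33.0 and 35.7 on the second. The question was which genes differ in expression between resistant and parental cells.

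The resistant line had lost the transcripts of several secreted proteins that were abundant in parental cells, carried more KRAS, EGFR and MYC mRNA, and showed changes in both directions among feedback genes of the MAPK pathway. CST1, which encodes a secreted cystatin protease inhibitor (chromosome 20, 23747553 to 23751268), fell from 1102 ± 58.3 to 0.384 ± 0.0901 CPM (SD, n = 3), with an adjusted p of 3.64e-14. TFF3, a trefoil peptide of mucous epithelia, fell from 403 ± 9.46 to 0.562 ± 0.299 CPM, and SRGN, the proteoglycan serglycin, from 824 ± 24.9 to 1.98 ± 0.495 CPM. In the other direction, MYC rose 3.25-fold, EGFR 3.1-fold and KRAS 1.85-fold. Of 19670 genes tested with edgeR, 10411 changed, 5789 of them higher and 4622 lower in resistant cells, and 4727 changed at least 2-fold, 3232 higher and 1495 lower. The groups did not overlap in 12163 genes (61.8%), where chance gives 10%.

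The count of higher genes went with reads at loci that are normally silent. Genes with a count numbered 19183, 20342 and 19873 in parental and 34216, 27246 and 35262 in resistant libraries 1 to 3, and olfactory receptor genes held 0.0019 ± 0.00057 RPM (reads scaled to library size) per exonic kb in parental and 0.082 ± 0.0534 in resistant libraries (n = 3). Among genes under 1 CPM, 1657 were higher and 40 lower. With a filter of 5 CPM in 3 libraries, 1675 genes changed at least 2-fold, 740 higher and 935 lower, and with background subtracted 3207 did, 1543 higher and 1664 lower. Without resistant library 2, the library with the fewest such reads among the resistant ones, 9649 genes changed at least 2-fold, and with it as the only resistant library 2792 did, 1137 higher and 1655 lower.

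**Figure D1:**
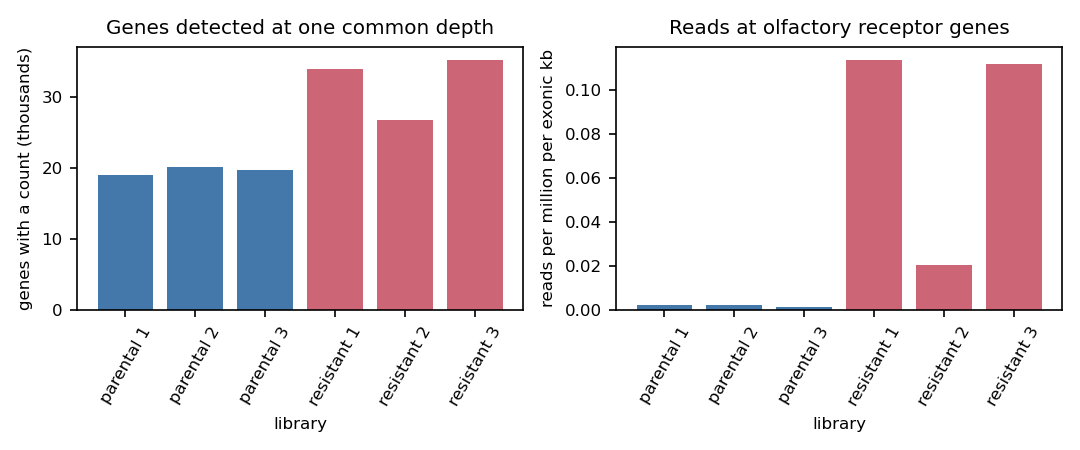
Left, genes with a count in each library after all libraries were thinned to the same total (bars). Right, RPM per exonic kb at 404 olfactory receptor genes, which lie at 0.0204 in resistant library 2 and at 0.114 and 0.112 in libraries 1 and 3.

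The 10 largest rises among genes of at least 10 CPM included receptors and signalling proteins. GABRG1, a subunit of the GABA-A receptor (chromosome 4, 46035769 to 46124081), had no parental read and 18.4 ± 0.616 CPM in resistant cells, at least 463-fold higher. IL1RL1, the receptor of interleukin-33, rose from 16 reads to 7331, a ratio of 509 (95% interval 313 to 891), and EMB, the membrane glycoprotein embigin, from 9 reads to 2477, a ratio of 306 (161 to 670). All parental reads of IL1RL1 were in library 1 and all those of EMB in library 2. Their log2 fold changes in edgeR were 8.92 ± 0.589 (SE) and 8.21 ± 0.515. MDGA1, SLITRK5, PARP8, IL11, BMP6, CEACAM5 and COBLL1 had log2 fold changes of 6.06 ± 0.12 (SE), 5.68 ± 0.20, 5.48 ± 0.20, 5.42 ± 0.17, 5.15 ± 0.18, 5.10 ± 0.18 and 5.09 ± 0.16. The cytokine IL11 went from 0.544 to 23.3 CPM and the growth factor BMP6 from 0.95 to 33.6 CPM. PTPRM, a receptor tyrosine phosphatase among the 3 lowest p-values, rose 18.7-fold to 243 ± 13.7 CPM (adjusted p = 3.92e-12).

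Among the 10 largest falls, SAA1, the acute-phase protein serum amyloid A, fell from 26828 to 12 reads, a ratio of 2010 (95% interval 1150 to 3890). SPINK4 fell from 4399 to 3 reads (ratio 1320, 451 to 6400) and CST4, a paralog of CST1, from 3698 to 12 (ratio 277, 159 to 537). HTRA1, a secreted protease, went from 85.3 ± 3.31 to 0.16 ± 0.108 CPM, MAGED1 from 50.5 ± 7.34 to 0.184 ± 0.23, EPB41L2 from 112 ± 6.73 to 0.548 ± 0.344 and DEFB1, an epithelial defensin, from 29.2 ± 0.984 to 0.233 ± 0.0479.

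The drug's target and its partner were both higher. KRAS (chromosome 12, 25204789 to 25250936) rose from 109 ± 2.4 to 201 ± 6.38 CPM, a log2 fold change of 0.89 ± 0.06 (SE, adjusted p = 9.41e-08), and PPIA (chromosome 7, 44796680 to 44824564) from 1973 ± 98 to 3182 ± 213 CPM, 0.69 ± 0.07 (adjusted p = 6.91e-06). KRAS overlaps ETFRF1, which fell by 0.29. PPIA and EGFR lie in a stretch of chromosome 7 (44379121 to 55942530) where 16 of the 20 expressed genes around TNS3 had a log2 fold change above 0 (median 0.97). Whether PPIA and EGFR rose apart from this neighbourhood was not tested. In the list of inhibitor target and partners, 4 of 6 genes rose and 1, PPIB, fell from 444 to 262 CPM (5 adjusted over the list alone, camera adjusted p = 0.51). Without parental library 3 or resistant library 2, 2 of 6 rose. Of 27 RAS pathway components, 9 rose, 7 fell and 11 did not pass (16 adjusted over the list alone, camera adjusted p = 0.934). SHOC2, a scaffold that promotes RAF activation, fell by 1.25, RAF1 by 0.79 and MAP2K2 by 0.94 on the log2 scale, and BRAF rose by 0.57. Of the 9 that rose, RASGRP1 and KSR2 had no parental read and under 2 CPM in resistant cells.

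Genes driven by MAPK signalling moved both ways. Of 21, 8 rose and 10 fell (19 adjusted over the list alone), and the list was not called (camera adjusted p = 0.419, but 0.0462 without resistant library 2 and 0.00764 with no filter). DUSP6, a phosphatase of ERK, fell from 129 ± 0.965 to 31.3 ± 1.81 CPM (log2 fold change -2.04 ± 0.07, adjusted p = 2.61e-10), the cyclin CCND1 from 203 ± 3 to 49.2 ± 10.2 (-2.04 ± 0.12), the ETS factor ETV5 by 1.01 ± 0.07 on the log2 scale and ETV4 from 27.3 ± 0.845 to 19.9 ± 1.76. The feedback inhibitor SPRY4 rose from 98.8 ± 5.34 to 129 ± 15.9 CPM, the AP-1 member FOSL1 from 106 ± 12.8 to 513 ± 60.4, EGR1 from 84.4 to 239, and MYC from 272 ± 11.3 to 882 ± 102 (1.70 ± 0.08, adjusted p = 7.21e-09). DUSP4 stood at 371 and 344 CPM (adjusted p = 0.164).

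Receptor tyrosine kinases and their ligands changed both ways. Of 22 receptors 11 rose and 5 fell (18 adjusted over the list alone, camera adjusted p = 0.498), and 4 of those that rose were under 2 CPM in resistant cells. With background subtracted 7 of 19 rose and 5 fell, and without resistant library 2, 18 of 28 rose. EGFR rose from 391 ± 26.3 to 1212 ± 93.7 CPM (log2 fold change 1.63 ± 0.08) and IGF1R from 57.5 ± 6.19 to 152 ± 5.16 CPM (1.41 ± 0.08). MST1R, AXL and MET rose by 1.21, 0.86 and 0.77 on the log2 scale, while MERTK fell from 6.06 to 1.52 CPM. Of 20 ligands 5 rose and 4 fell (9 adjusted over the list alone, camera adjusted p = 0.995), and with background subtracted 5 rose and 6 fell of 18. Without resistant library 2, 8 of 24 rose. AREG, a ligand of EGFR, rose from 39.0 ± 0.792 to 162 ± 41.2 CPM, and GAS6, the ligand of AXL and MERTK, fell from 103 ± 2.61 to 17.4 ± 1.51. In the PI3K, AKT and mTOR list, 9 of 30 rose and 8 fell (17 adjusted over the list alone, camera adjusted p = 0.934). DEPTOR, an inhibitor of mTOR, rose from 4.77 ± 0.47 to 31.3 ± 3.31 CPM, and the lipid phosphatase INPP4B fell from 54.1 ± 2.8 to 10.6 ± 1.27.

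**Figure D2:**
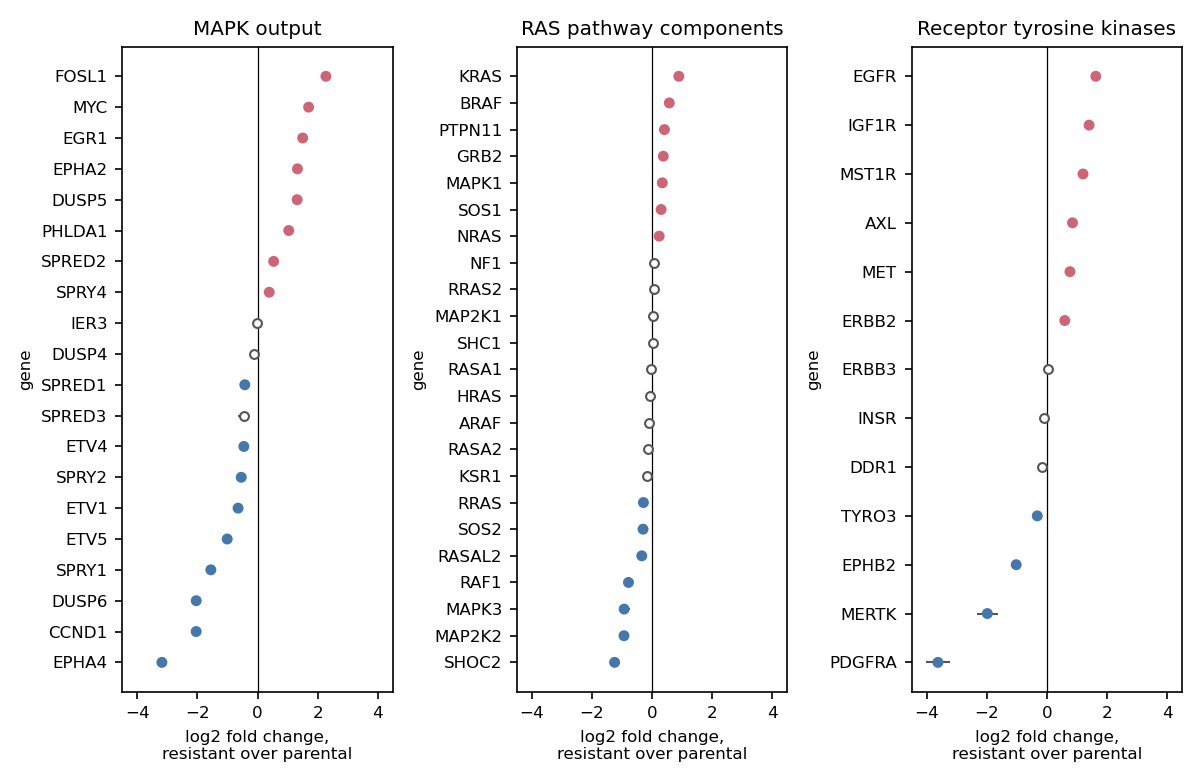
Log2 fold change, resistant over parental (points, with SE as bars), of genes of 3 lists with at least 5 CPM in the higher group. Filled points passed an adjusted p of 0.05 in edgeR (red higher, blue lower) and open points did not, and EGFR at 1.63 and DUSP6 at -2.04 stand toward opposite ends of their lists.

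Changes were uneven between chromosomes. Over 10206 protein-coding genes of at least 5 CPM, the median log2 fold change was highest on chromosome 18 at 0.77 (151 genes, 108 higher and 15 lower). It was lowest on chromosome 10 at -0.55 (414 genes, 57 higher and 286 lower).

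**Figure D3:**
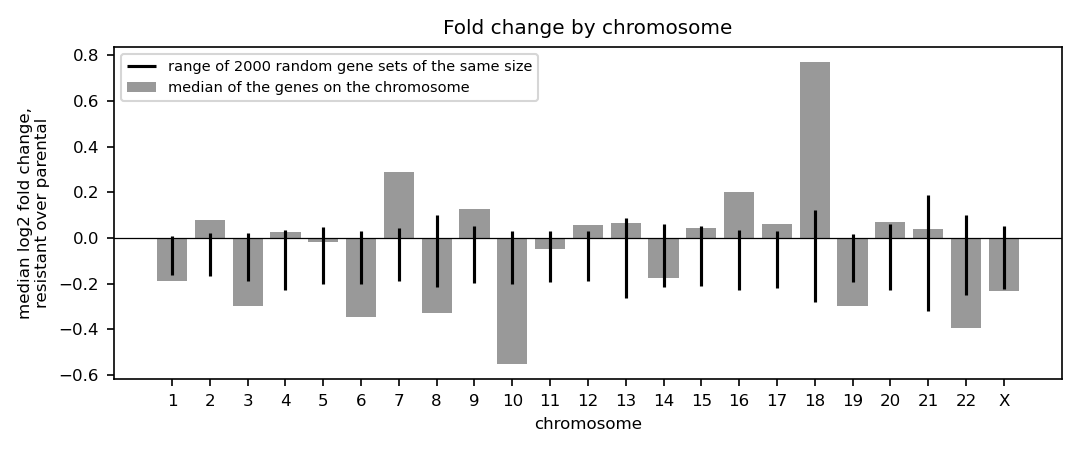
Median log2 fold change, resistant over parental, of protein-coding genes of at least 5 CPM on each chromosome (bars), with the range of 2000 random gene sets of the same size (lines). Chromosome 18 at 0.77 lies above its range, as do chromosomes 2, 7, 9, 12, 16, 17 and 20. Chromosome 10 at -0.55 lies below its range, as do chromosomes 1, 3, 6, 8, 19, 22 and X.

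Camera called 8 of the 35 lists, 2 higher and 6 lower. Squamous and basal markers rose in 12 of 15 tested genes and fell in 1 (13 adjusted over the list alone, camera adjusted p = 0.00251, adjusted p = 0.97 with an estimated correlation). KRT17 rose from 4.77 ± 0.417 to 78.3 ± 6.9 CPM, TRIM29 from 2.00 ± 0.244 to 22.7 ± 1.31 and the desmosomal protein DSP from 2.58 ± 0.469 to 13.8 ± 1.56, whereas TP63, the master regulator of basal cells, fell from 2.00 ± 0.319 to 0.627 ± 0.344. Of the 12 that rose, 4 were under 2 CPM in resistant cells, and with background subtracted 8 of 12 rose and 1 fell (0.00769). Among MYC targets, which serve ribosome production and nucleotide synthesis, 18 of 25 rose and 4 fell (22 adjusted over the list alone, camera adjusted p = 0.0499, adjusted p = 0.97 with an estimated correlation and 0.0792 with a replicate block). CAD, which starts pyrimidine synthesis, rose from 68.5 ± 2.87 to 148 ± 12.7 CPM, ODC1 from 382 ± 36.1 to 823 ± 42 and POLR1B from 47.4 ± 3.13 to 91.2 ± 3.46, while BOP1 fell from 58.6 ± 2.42 to 41.9 ± 2.32.

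Proliferation genes fell in 19 of 32 and rose in 6 (25 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.97 with an estimated correlation). MCM4 of the replicative helicase fell from 250 ± 8.57 to 81.5 ± 2.79 CPM, CDK1 from 263 ± 15 to 116 ± 8.4 and CDC45 from 69.4 ± 6.06 to 28.1 ± 3.68, and TYMS rose from 46.6 ± 1.87 to 105 ± 4.29. Antigen presentation genes fell in 14 of 23 and rose in 4 (20 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.97 with an estimated correlation). B2M, the light chain of HLA class I, fell from 591 ± 12.5 to 245 ± 21.7 CPM, HLA-A from 224 ± 14.5 to 113 ± 6.25 and HLA-DMB from 56.2 ± 4.82 to 15.7 ± 2.92, and the peptide transporter TAP2 rose from 34.5 ± 3.92 to 68.5 ± 7.51. Interferon response genes fell in 12 of 33 and rose in 7, of which 4 were under 2 CPM (19 adjusted over the list alone, camera adjusted p = 0.0499, adjusted p = 0.97 with an estimated correlation). With background subtracted 14 of 29 fell and 3 rose (0.0403). Without parental library 1, 2 or 3, 4 of 33 rose, and without resistant library 1 or 3, 3 did. GBP2 fell from 21.2 ± 2.86 to 3.71 ± 0.171 CPM, IFI44 from 17.9 ± 1.05 to 6.68 ± 1.17 and ISG15 from 10.9 ± 0.53 to 2.85 ± 0.706, and the RNA sensor IFIH1 rose from 6.32 ± 0.857 to 15.2 ± 0.809.

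Ribosomal protein genes fell in 22 of 30 and rose in 2 (24 adjusted over the list alone, camera adjusted p = 0.000273, adjusted p = 0.97 with an estimated correlation). RPS28 fell from 997 ± 79.1 to 492 ± 40.6 CPM, RPL8 from 926 ± 75.1 to 525 ± 22.2 and RPL35 from 706 ± 35.6 to 367 ± 44.6, and RPL13 rose from 886 ± 23 to 1403 ± 86. Histone genes, listed beforehand as a sign of RNA without poly(A), fell in 13 of 15 and rose in 1 (15 adjusted over the list alone, camera adjusted p = 0.000225, adjusted p = 0.97 with an estimated correlation). Proliferation genes fell as well, and the histone genes named here lie on chromosome 6, where 57.1% of protein-coding genes of at least 5 CPM were lower. Whether the fall of histone genes marks RNA quality was not tested. H2BC9, at 77.4 ± 4.1 CPM in parental cells, was 2.21-fold lower in resistant cells, H1-3 from 106 ± 3.46 to 50.1 ± 3.6 and H1-5 from 568 ± 27 to 341 ± 4.88. H4C3 rose from 59.5 ± 8.94 to 74.4 ± 7.2 CPM, a call lost without parental library 1 (adjusted p = 0.105), parental library 2 (0.139) or resistant library 2 (0.199), when 0 of 15 histone genes rose. Mitochondrial mRNAs fell in 8 of 13 (8 adjusted over the list alone, camera adjusted p = 0.00864, adjusted p = 0.97 with an estimated correlation). MT-ND3 fell from 2291 ± 113 to 1285 ± 160 CPM, and MT-ATP8, MT-CO3 and MT-ATP6 fell by 0.73, 0.63 and 0.68 on the log2 scale. Mitochondrial mRNA made up 18.4 ± 1.37% of counts in parental and 15.8 ± 1.34% in resistant libraries (SD, n = 3).

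Of these 8 calls, the filter of 5 CPM ended 4, with adjusted p of 0.0568 for proliferation, 0.218 for interferon response, 0.115 for antigen presentation and 0.0883 for mitochondrial mRNAs. Their median log2 fold changes with this filter were -0.238, -0.443, -0.692 and -0.56 in that order. In the main fit they were -0.303, -0.366, -0.463 and -0.621, so the calls ended while the falls remained. Background subtraction ended the calls of antigen presentation (0.122) and mitochondrial mRNAs (0.062), whose medians were then -0.661 and -0.548. The MYC target call ended without parental library 1 (0.171), 2 (0.28) or 3 (0.319), without resistant library 2 (0.691) and with no filter (0.38). The MYC target median in these settings was 0.45, 0.383, 0.331, 0.341 and 0.364, against 0.419 in the main fit. With resistant library 2 alone the mitochondrial median was -0.444. With no filter, where the median log2 fold change of all genes was 2.16, 8 more lists passed as lower than other genes: MAPK output (0.00764), PI3K (0.0488), epithelial (0.0307), TGF-beta (0.0286), NF-kB (0.00197), NRF2 (0.0158), autophagy (0.00968) and drug transporters (0.0021).

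**Figure D4:**
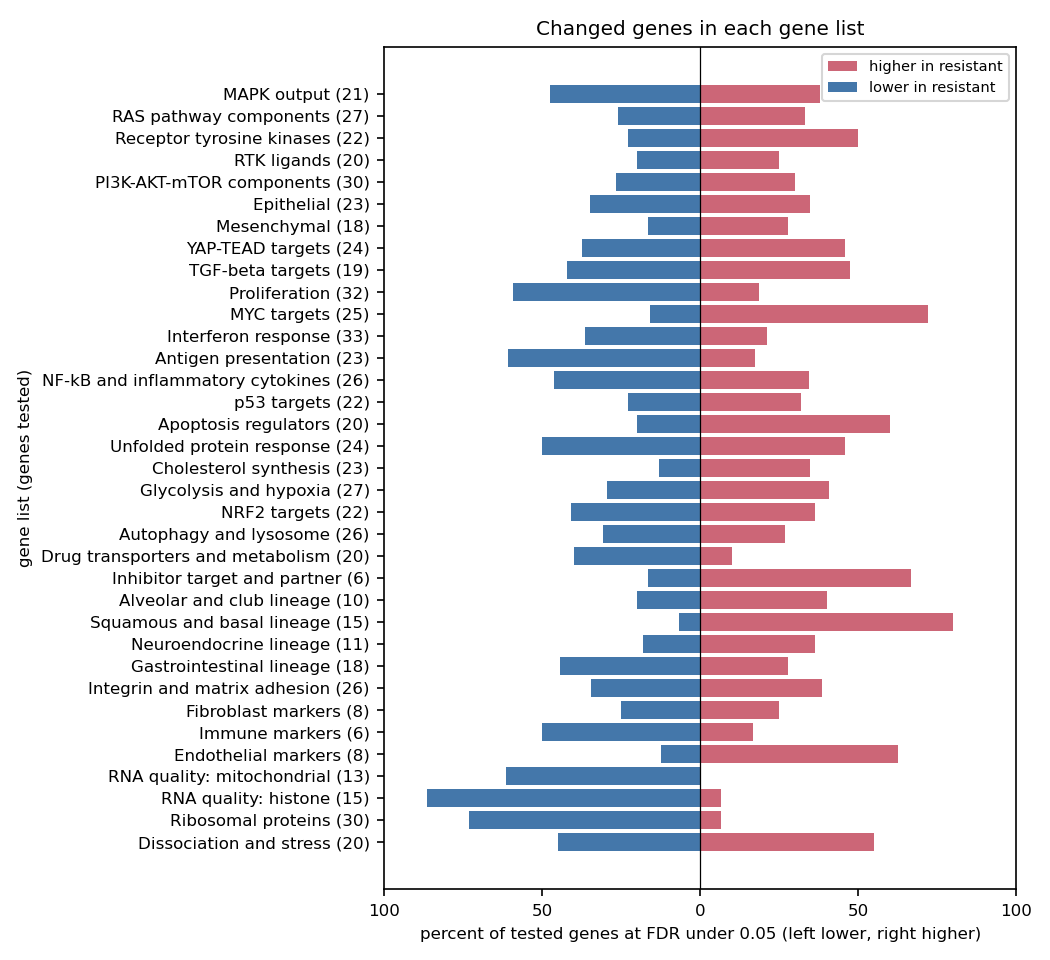
Percent of tested genes that changed in each of the 35 lists (bars, higher to the right and lower to the left, adjusted p under 0.05 in edgeR), with the number tested in brackets. Squamous and basal markers reach furthest to the right with 12 of 15 genes, and histone genes furthest to the left with 13 of 15.

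Of 24 genes of the unfolded protein response list, 11 rose and 12 fell (23 adjusted over the list alone, camera adjusted p = 0.804). Among those that rose, TRIB3 went from 9.83 ± 0.88 to 85.3 ± 4.78 CPM, the asparagine synthetase ASNS from 9.45 to 62.3 and CHAC1 from 1.09 to 7.41. Among those that fell, MANF went from 66.9 ± 9.07 to 14.3 ± 1.34 CPM, CRELD2 from 46.1 to 14.9, HSP90B1 from 716 to 451 and HSPA5 from 526 to 349. Dissociation and stress genes rose in 11 of 20 and fell in 9 (20 adjusted over the list alone, camera adjusted p = 0.964). JUN rose from 38.3 ± 3.49 to 146 ± 11 CPM, and the co-chaperone BAG3 fell from 129 ± 8.02 to 55.9 ± 4.1.

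Gastrointestinal markers fell in 8 of 18 and rose in 5, of which 3 were under 2 CPM (15 adjusted over the list alone, camera adjusted p = 0.285). With the filter of 5 CPM 8 of 9 fell and 1 rose (0.0201), and with background subtracted 10 of 15 fell and 2 rose (0.108). Without resistant library 1 or 3, 3 of 18 rose. Beside TFF3, the gastric mucin MUC6 fell from 1215 ± 349 to 40.4 ± 5.43 CPM and AGR2, a protein disulfide isomerase of mucous cells, from 404 to 10.7, while CEACAM5 rose from 1.14 ± 0.343 to 39.2 ± 3.95. Epithelial genes rose in 8 of 23 and fell in 8 (16 adjusted over the list alone, camera adjusted p = 0.593). MUC1 fell from 412 ± 15.4 to 83.6 ± 14 CPM and ELF3 from 42.9 ± 0.313 to 3.65 ± 1.14. Mesenchymal genes rose in 5 of 18 and fell in 3 (8 adjusted over the list alone, camera adjusted p = 0.878). Without parental library 1, 9 of 25 rose, without parental library 3, 8 of 25, and without resistant library 2, 11 of 24. SERPINE1 rose from 11.3 ± 1.32 to 45.3 ± 3.18 CPM and TGFBI fell from 29.1 ± 2.87 to 5.82 ± 0.187. VIM stood at 944 and 928 CPM. Alveolar and club markers rose in 4 of 10 and fell in 2 (6 adjusted over the list alone, camera adjusted p = 0.535), and with background subtracted 2 of 8 rose and 2 fell. Without parental library 1 or 3, 7 of 20 rose, and without resistant library 2, 13 of 20. FOXA1 rose from 13.4 ± 1.03 to 27.3 ± 1.9 CPM and BPIFB1 from 0.734 ± 0.361 to 4.80 ± 1.54. Neuroendocrine markers rose in 4 of 11, 3 of them under 2 CPM, and fell in 2 (6 adjusted over the list alone, camera adjusted p = 0.995), and with background subtracted 1 rose and 4 fell of 7. Of 18, 7 rose without parental library 1 or 2, 9 without parental library 3 and 11 without resistant library 2. CHGB rose from 57.7 ± 5.84 to 127 ± 9.97 CPM and STMN1 fell from 270 ± 15.4 to 82.7 ± 2.06.

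Survival genes and cytokines changed in both directions. Apoptosis regulators rose in 12 of 20 and fell in 4 (16 adjusted over the list alone, camera adjusted p = 0.434, and 0.0236 with the filter of 5 CPM). The anti-apoptotic MCL1 rose from 182 ± 7.39 to 807 ± 37.3 CPM and BCL2 from 3.12 ± 0.214 to 12.2 ± 0.751. NF-kB targets and cytokines rose in 9 of 26 and fell in 12 (22 adjusted over the list alone, camera adjusted p = 0.272, but 0.00581 without resistant library 2 and 0.00197 with no filter). TNFAIP2 fell from 114 ± 1.51 to 21.6 ± 2.32 CPM, CXCL1 from 177 to 15.4 and IL6 from 44.8 to 12.3, and TNFAIP3 rose from 37.5 to 186. Targets of p53 rose in 7 of 22 and fell in 5 (12 adjusted over the list alone, camera adjusted p = 0.955). SESN2 rose from 3.88 ± 0.508 to 22.4 ± 2.17 CPM and CDKN1A from 21.9 ± 0.931 to 52.9 ± 3.48.

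Targets of YAP and TEAD rose in 11 of 24 and fell in 9 (22 adjusted over the list alone, camera adjusted p = 0.849). WWTR1, which encodes TAZ, rose from 261 ± 4.48 to 602 ± 1.91 CPM, and TGFB2 fell from 63.3 ± 5.21 to 10.6 ± 0.359. Targets of TGF-beta rose in 9 of 19 and fell in 8 (17 adjusted over the list alone, camera adjusted p = 0.515), and BMP4 fell from 43.6 ± 2.5 to 2.01 ± 0.406 CPM. Integrin and matrix adhesion genes rose in 10 of 26 and fell in 9 (19 adjusted over the list alone, camera adjusted p = 0.955). ITGB4, a subunit of the laminin receptor of hemidesmosomes, rose from 100 ± 8.37 to 448 ± 10.5 CPM and ITGA3 from 121 ± 10.6 to 375 ± 16.1.

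Cholesterol synthesis genes rose in 8 of 23 and fell in 3 (11 adjusted over the list alone, camera adjusted p = 0.934). PCSK9 rose from 37.6 ± 1.44 to 254 ± 11.9 CPM and SQLE fell from 91.7 ± 2.92 to 39.1 ± 1.88. Glycolysis and hypoxia genes rose in 11 of 27 and fell in 8 (22 adjusted over the list alone, camera adjusted p = 0.964), and 7 rose without parental library 2 or 3. NDRG1 rose from 16.8 ± 1.4 to 168 ± 14.2 CPM and the carbonic anhydrase CA12 fell from 44.0 ± 3.17 to 1.98 ± 0.873. Targets of NRF2 rose in 8 of 22 and fell in 9 (17 adjusted over the list alone, camera adjusted p = 0.51). The cystine transporter SLC7A11 rose from 77.5 ± 0.644 to 188 ± 12.7 CPM and NQO1 fell from 219 ± 21.7 to 72.7 ± 7.42. Autophagy and lysosome genes rose in 7 of 26 and fell in 8 (15 adjusted over the list alone, camera adjusted p = 0.593). MAP1LC3B rose from 53.7 ± 1.82 to 194 ± 12.8 CPM and GLB1 fell from 57.6 ± 1.54 to 26.6 ± 0.806. Drug transporters and metabolism genes fell in 8 of 20 and rose in 2, both under 2 CPM (10 adjusted over the list alone, camera adjusted p = 0.0583). Without resistant library 1 or 3, 1 of 20 rose, and without resistant library 2, 4 of 22. The list passed with no filter (0.0021), with library-size scaling (0.0355), without parental library 2 (0.0392) or 3 (0.0148) and without resistant library 2 (0.0462) or 3 (0.0255). UGT1A1 fell from 13.6 ± 1.97 to 0.231 ± 0.115 CPM and TIPARP from 32.2 ± 2.58 to 9.42 ± 2.09.

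Endothelial markers rose in 5 of 8 and fell in 1 (6 adjusted over the list alone, camera adjusted p = 0.362), and all 5 that rose were under 2 CPM in resistant cells, among them ROBO4, with no parental read and 1.07 ± 0.54 CPM. PECAM1 fell from 25.5 ± 2.16 to 6.74 ± 0.561 CPM. Fibroblast markers rose in 2 of 8 and fell in 2 (4 adjusted over the list alone, camera adjusted p = 0.995), and with background subtracted 1 of 5 rose and 3 fell. Of 11, 5 rose without any 1 of the parental libraries and 6 without resistant library 2. COL1A1 rose from 18.5 ± 0.742 to 51.2 ± 8.08 CPM and PDGFRA fell from 5.72 ± 0.947 to 0.464 ± 0.268. Immune markers rose in 1 of 6 and fell in 3 (4 adjusted over the list alone, camera adjusted p = 0.362). Without parental library 2 or 3 or resistant library 3, 0 rose, and without resistant library 2, 3 of 10. LYZ fell from 1643 to 16 reads, a ratio of 92.4 (95% interval 56.7 to 162), and CD14 from 3.40 ± 0.954 to 0.619 ± 0.149 CPM. LYZ stood at 0.0264, 0.0127 and 0.257 CPM in resistant libraries 1 to 3, and its log2 fold change was -6.41 ± 0.616 (SE). In 11 of the 35 lists the median, the mean and the direction from camera differed in sign. They are the RAS pathway, PI3K, epithelial, p53, unfolded protein response, glycolysis, NRF2, autophagy, neuroendocrine, fibroblast and stress lists.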

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

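The tests of DNA-like background, of concentrated reads and of genes shared between libraries were chosen after the reads at silent loci had been seen, and the thinning test before. Reads appeared at olfactory receptor genes, which no comparison concerns, at a mean of 0.082 RPM per exonic kb in resistant libraries, above the 0.0019 in the parental controls. Depth is argued against, because with all libraries thinned to the same total the resistant ones still detected 1.63 times as many genes. Transcription from a small subset of the olfactory receptor genes is argued against. Over the 3 resistant libraries together, the top 10% of them held 34.5% of the reads, against 30.4% at a uniform rate, and 94.8% had a read. Within resistant library 1, however, reads fell on 74.8% of these genes at 7.96 reads per exonic kb. At that density a uniform rate would reach nearly all of them, if each read were a separate molecule. The reads carry no molecular identifiers, so copies of the same fragment could leave such gaps too. A broader subset therefore stays open, and the shortfall does not decide it. In other silent genes transcription of a subset stays open. The top 10% held 39.5% to 66.4% of the reads in 7 classes and all of them in snoRNA genes. In library 1 reads fell on 42.0% of lincRNA genes, against 97.1% at a uniform rate, which again takes each read as a separate molecule. The genes with reads in libraries 1 and 3 overlapped by 1.06 to 1.26 times the overlap after shuffling in protein-coding genes, lincRNAs, antisense genes and both kinds of pseudogene (permutation p = 0.0005 in each). The ratio was 7.86 in snoRNA genes (3 shared genes, permutation p = 0.0045). It was 0.813 and 0.879 in immunoglobulin and T cell receptor V genes, with 2 and 6 shared genes (permutation p = 0.749 and 0.766). Reads from DNA or another source that does not depend on transcription stay open as a candidate explanation, because a test of them decided nothing: the ratio of resistant library 2 to library 1 differed 10.6-fold between 4 silent families, from 0.0361 in T cell receptor segments (16 reads in library 2) to 0.382 in keratin-associated proteins, beyond the bound of 2 set for this test, but resampling genes, a step added after that value was seen, gave a 95% interval of 1.9 to 104. Low-level transcription of the whole genome in the resistant line also stays open and was not tested.

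All 9 gene classes without parental reads were also looked at, as values and not as a test. The ratio of library 2 to library 1, here in reads without scaling, was 0.208 to 0.221 in protein-coding genes, lincRNAs, antisense genes and both kinds of pseudogene, 0.178 and 0.0405 in immunoglobulin and T cell receptor V genes, and 0.875 and 0.887 in miRNA genes (7 reads in library 2 and 8 in library 1) and snoRNA genes. Library 1 held 5.49 to 8.08 reads per exonic kb in the first 5 classes, 3.13 in immunoglobulin and 6.66 in T cell receptor V genes, and 0.0522 in miRNA and 1.28 in snoRNA genes. These last have median exonic lengths of 80 and 104.5 bases, and because the counting method is not known, the density in genes so short does not decide between the explanations.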

How the results depend on the processing

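Background subtraction and the fit with resistant library 2 as the only resistant library were chosen after the data were seen, and the other alternatives before. Of 107 named genes, 106 kept their direction and side of the threshold in each alternative that tested them, H4C3 being the exception. Most of them were named for a low adjusted p or a large change, so this does not measure the stability of all calls. Of all 10411 calls, 8906 to 9592 were kept when each library was left out in turn. BPIFB1, CD14, PDGFRA, ROBO4 and TP63 were not tested with the filter of 5 CPM, and glmTreat was run for counts alone. No call of a named gene or a list reversed, but the balance of changed genes did: 3661 were higher and 3820 lower with the filter of 5 CPM, 4353 and 4587 with background subtracted, and 3225 and 3814 with resistant library 2 alone. The count of changed genes, 10411, was 7039 to 15026 in the alternatives that test for any change, and 5032 with glmTreat, which tests for more than 1.5-fold. The count changed at least 2-fold, 4727, was 8394 without a filter, 1675 with at least 5 CPM, where 10560 genes were tested, and 2792 with resistant library 2 alone, assumed to vary like the parental group. Leaving out each library in turn gave 9396 to 15026 changed genes, 4402 to 9649 changed at least 2-fold, the highest without resistant library 2, and 7 to 10 lists. It moved the count of higher genes by over 1.5 times in 13 lists and that of lower genes in 0. The share of higher genes among those changed at least 2-fold, 68.4%, was 80.9% without a filter, 44.2% with at least 5 CPM, 48.1% with background subtracted and 40.7% with resistant library 2 alone, and the cause was not tested for the filter. Library-size scaling moved the median log2 fold change of all genes from 0.15 to 0.281 and gave 6766 higher and 3730 lower genes (64.5% higher). The lists called, 8, were 15 without a filter, 0 with a correlation estimated per list and 24 with fry, which tests each list by itself, and the cause was not tested. In the 8 called lists the estimated correlation was 0.064 (interferon response) to 0.85 (mitochondrial mRNAs), above the preset 0.01. The DESeq2 Wald test called 10734 genes, limma-voom 10939, and glmTreat gave 4144 at 2-fold. The labels give both groups replicate numbers 1 to 3. Deviations from the group mean had correlations of 0.008, -0.025 and 0.012 between same-numbered libraries. They gave no sign of pairing, but 3 libraries per group are too few to exclude it. A replicate block gave 9604 changed genes, 4254 at least 2-fold and 7 lists. Depth may limit genes under 1 CPM. In the resistant libraries, reads at the density of silent loci, whatever their source, are of the same order as the counts of such genes.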

Other observations

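The tests of the KRAS neighbourhood, GC content and copy number were chosen after the values were seen, and those of scaling and sample splits before. Background subtraction was added after the data were seen, though its prediction for chromosome 18 was recorded as written beforehand. The contrast between lines was close to all or none for a set of protein-coding genes chosen here after their values were seen. Of these, 43 had over 10 CPM in parental and under 1 CPM in resistant cells, and 14 the reverse. Beside the genes named in the report, SPP1, the matrix protein osteopontin, went from 74.5 to 0.99 CPM, and the cystatin CST2 from 25.8 to 0.236. In the other direction the chemokine receptor ACKR3 went from 0.697 to 22.2 CPM and the kinase STK26 from 0.856 to 26.2.

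Median fold changes differed between chromosomes. Only medians per chromosome were compared, so a shift of a whole chromosome cannot be told from a shift of a part of it. Over 10206 protein-coding genes of at least 5 CPM, the median log2 fold change on chromosome 18 was 0.77, where 2000 random sets of that size ranged from -0.28 to 0.12, and that on chromosome 10 was -0.55, where they ranged from -0.20 to 0.03. Most other chromosomes also lay outside their ranges, among them chromosome 12 with KRAS (0.057, above 0.029) and chromosome 7 with PPIA and EGFR (0.288, above 0.045). Chromosome 12 had 197 genes higher and 162 lower. For chromosome 18, the only one tested, GC content and background are argued against as the whole cause. Its median was 0.834 after a GC correction and 0.782 after background subtraction. The GC correction recentred all genes, moving chromosome 10 to -0.476 as well, so 0.834 is not a gain. Background, at a mean of 0.082 RPM per exonic kb in resistant libraries, is small beside 5 CPM, so its subtraction could move these medians little. A change of chromosome copy number may be involved, since silent loci in the 8 windows with the highest medians held 1.48 times the reads, relative to GC expectation, of the 8 lowest (two-sided exact permutation p = 0.0434, over windows that share chromosomes and are not independent, 4 of the highest being on chromosome 18 and 4 of the lowest on chromosome 10; pooled over genes, which are not independent either, 1.70, 95% interval 1.45 to 2.01), and over 23 chromosomes this measure had a Spearman rho of 0.469 with the fold change (permutation p = 0.0251). It stays open, because the measure looked at first, the median density per chromosome, gave a rho of 0.188 (permutation p = 0.39). Only 5 of the 8 highest windows, and 2 of the 8 lowest, lay above expectation. The silent loci were chosen for having no read in any parental library, so parental cells give no baseline.

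KRAS rose with some genes beside it, RASSF8 from 1.42 to 23.9 CPM and ITPR2 from 3.48 to 35.5, both chosen after their values were seen. The 10 expressed genes on each side, between 20369245 and 27756295 on chromosome 12, had a median log2 fold change of 0.185, with 10 of the 20 higher, where 29.6% of genes at this level were, and 4 lower. A rise of the whole neighbourhood as large as that of KRAS is argued against, because resampling the 20 genes gave an upper 95% bound of 0.385 for that median. KRAS kept a log2 fold change of at least 0.911 under the other scalings. Both of them raised the median of all genes, from 0.15 to 0.172 with DESeq2 size factors and 0.281 with library-size scaling. They could not have lowered KRAS, so this check does not decide on scaling. A smaller rise of the neighbourhood stays open, because the median lay at the 84.6th percentile of 9746 such windows with a resampled 95% interval from the 41.7th to the 94.7th, a spread added after the percentile was seen. A copy gain limited to KRAS and regulation in the resistant line stay open as hypotheses and were not tested. Other named genes lie in the 8 windows with the highest medians, among them PPIA and EGFR on chromosome 7, PTPRM, TYMS and BCL2 on chromosome 18, and MAP1LC3B on chromosome 16. Named genes also lie in the 8 windows with the lowest medians. Among them are CDC45 on chromosome 22 and BAG3 on chromosome 10, which fell, and TAP2 on chromosome 6, which rose. The neighbourhoods of all these genes were not tested as that of KRAS was.

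Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 10411 changed genes, and the highest of the others gave 0 in edgeR. With 10 splits, no share under 0.05 can be reached.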
